A study of Homo sapiens with 11 samples.

How the data were processed

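RNA-seq was run on primary human aortic endothelial cells (HAEC), the cells that line the aorta. Per the labels' protocols, cells of 3 donors were pooled and grown in technical replicates, so each p-value measures the spread between replicate cultures of a single donor pool and not the spread between people. Cells at 50 to 60% confluency were transfected for 12 h with a microRNA-33 (miR-33) mimic, a synthetic duplex that raises the activity of that microRNA, or with a control mimic. RNA was taken 72 h after transfection. TNF, an inflammatory cytokine, was given at 10 ng/mL for the last 24 h, and native low-density lipoprotein (nLDL) at 50 mg/dL of cholesterol for the last 48 h. RNA was isolated with Trizol and a miRNeasy kit and libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols.

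The 11 libraries fell into 4 groups: control mimic without stimulus (untreated, n = 3), control mimic with TNF (n = 2), control mimic with TNF and nLDL (n = 3), and miR-33 mimic with TNF and nLDL (n = 3). No library analysed here combined the miR-33 mimic with the untreated, TNF-only or nLDL-only state, so effects of the mimic were measured only under both stimuli.

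Per the submitters' processing notes, STAR, Partek and the GRCh38 (hg38) build were used. Their versions, the annotation release, the counting settings and the use of strand are not given in the sources used here. The deposited table holds estimated counts per gene for 26225 genes, 5855 of them without a gene name, as the table itself shows: between 38.2% and 41.1% of all values in each library, those of 0 included, are not whole numbers. It also holds 13 empty columns, which were not used. The estimated counts were rounded to whole numbers. Start positions matched GENCODE 29 for 18617 genes, and for 15075 of these the end in the table lay a single base beyond the annotated end, so ends are given here with that base removed. Because the strand setting is not given, values of genes that overlap another gene are uncertain where the other gene is highly expressed. Genes are named as overlapping where the count of the other gene was 20% or more of their own, a limit set after seeing the data.

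Library totals ran from 19743058 to 26496729 estimated counts, and 3 counts corresponded to 0.115 to 0.147 CPM (counts scaled to a common library total), the level below which a gene is hard to tell from absent. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A single unnamed locus on the minus strand of chromosome 21 (8393419 to 8394341) held 5.01 to 8.98% of the counts of a library. RefSeq places it inside RNA18SN3, a ribosomal RNA gene, and its 11 values are stored with 3 digits only.

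Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by filterByExpr (17395) entered a single quasi-likelihood fit of all 11 libraries with TMM scaling and group means as the model, so that the TNF group with 2 libraries borrowed its spread from the other groups. The 4 comparisons were TNF against untreated, TNF with nLDL against TNF, TNF with nLDL against untreated, and miR-33 mimic against control mimic under TNF with nLDL. A gene was called when its Benjamini-Hochberg adjusted p, taken within a comparison, was under 0.05. CPM values are TMM scaled and are given as mean ± SD, and log2 fold changes are given ± SE.

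The design, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Per comparison the text names the 6 called genes with the largest rise and the 6 with the largest fall among genes with a mean of 5 CPM or more in either group and no overlap between the groups. It also names the 2 most changed called members of each list with 3 or more called members, and, called or not, SREBF1, SREBF2, ABCA1, ABCG1, CPT1A, CROT, VCAM1, ICAM1, SELE, CCL2, CXCL8, KLF2 and NOS3. Unnamed, antisense and small RNA loci were passed over, and a few genes that the rule names are not reported here. Other genes are named only where the text says that they were chosen after their values were seen, or as called members of a short group.

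The 21 lists were leukocyte adhesion, chemokines and cytokines, NF-kB pathway and feedback, interferon response, antigen presentation by MHC class I, cholesterol synthesis and uptake (targets of SREBP2), cholesterol efflux with LXR targets, fatty acid synthesis (targets of SREBP1), fatty acid oxidation, reported miR-33 targets, endothelial identity, endothelial to mesenchymal transition, cell cycle, autophagy and lysosome, unfolded protein response, coagulation and fibrinolysis, and markers of smooth muscle, fibroblasts, leukocytes and lymphatic endothelium, with mitochondrially encoded mRNAs. Members are textbook genes of each process. Lists with 5 or more tested members were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 20 lists of a comparison. The leukocyte list had 4 tested members and no set test. Camera with an estimated correlation and fry were run beside it, and a list is described as moving as a set only where the call held with the estimated correlation.

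Genes that rose or fell with TNF by a log2 fold change of 1 or more were tested as 2 sets in the mimic comparison, which shares no library with the TNF comparison. Both take each gene's spread from the common fit, so their calls are not independent. Sites for miR-33 were searched in the longest annotated 3′ UTR, of 50 bases or more, of 12824 protein-coding genes of GENCODE 29. The 7-base site CAATGCA pairs with nucleotides 2 to 8 of miR-33a and of miR-33b, whose sequences were found in the reference hairpins. The mean log2 fold change of genes with a site minus genes without it, after regression on log UTR length and GC content and their squares (Python 3.11.15, numpy 2.4.6), was ranked among other 7-mers present in a similar number of genes.

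The steps were tested on simulated counts with 200 changed genes per comparison. These simulations were made after the measured counts had first been fitted, and the draws without a shifted list were added later still. In the simulated mimic comparison 53.7% of genes changed 1.5-fold, 86.6% of genes changed 2-fold and 100% of genes changed 4-fold were called, with 15 calls among 17165 other genes. In the simulated TNF with nLDL against TNF comparison the shares were 64.2%, 83.6% and 97.0%, with 11 false calls. They were 62.7%, 82.1% and 98.5% (8 false calls) for TNF against untreated, and 71.6%, 89.6% and 98.5% (11 false calls) for TNF with nLDL against untreated. The measured counts of these last comparisons gave 7597 and 8527 calls, far above 200. Recovery and false calls at such a share of changed genes were not simulated. A list shifted by 0.3 on the log2 scale was called in each of the 4 simulations. Over 10 further draws per comparison with no list shifted and the changed genes drawn outside the lists, 0 of 200 list tests were called. With the changed genes drawn from all genes, 6 to 9 of 200 were called, so a few strongly changed members can carry a camera call at the preset correlation. Counts were drawn independently for each gene, so these draws cannot show how often correlated genes give a false list call. A site effect of −0.2 planted in shuffled fold changes was recovered as −0.179. With none planted it was −0.0005, with 3020 other 7-mers as low. The shuffling removed any link of fold changes to UTR length and GC content. An effect as small as the measured one was not planted.

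Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, no filter and a stricter filter on low counts, a fit of the 2 compared groups only, the replicate number as a block, a test against a fold change of 1.2 (glmTreat), and leaving out each library in turn with the same genes kept. Leaving out the chromosome 21 locus, leaving out members shared by the lists of miR-33 targets and fatty acid oxidation, and recomputing the site effect under these fits, were added after seeing the data.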

Results

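The series asks how miR-33, a microRNA encoded within the SREBF genes of sterol control, acts on endothelial cells under inflammation and lipid load. Cultured HAEC carried a control mimic without stimulus (n = 3), with TNF (n = 2) or with TNF and nLDL (n = 3), or carried the miR-33 mimic with TNF and nLDL (n = 3). Estimated counts summed to 22164141, 23326273 and 19743058 in untreated replicates 1 to 3, and to 22566368 and 24152970 in TNF replicates 1 and 2. They summed to 25481926, 22359167 and 22382609 in TNF with nLDL replicates 1 to 3, and to 23944323, 26496729 and 22055735 in miR-33 mimic replicates 1 to 3. The first principal component of log2 CPM held 65.2% of the variance. Within every group, replicate libraries differed by more than sampling noise, with chi-square per degree of freedom from 3.26 to 24.2 over pairs, and none was counted as a repeat of another. Untreated replicate 1 stood apart, at up to 24.2 against the other untreated libraries, which stood at 4.66 against each other. All genes of the mitochondrial chromosome together took 5.40% ± 0.261 (SD, n = 3) of counts in untreated cells, 4.25% ± 0.237 (SD, n = 2) with TNF, 4.15% ± 0.273 (SD, n = 3) with TNF and nLDL, and 4.26% ± 0.0583 (SD, n = 3) with the miR-33 mimic.

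TNF raised adhesion molecules and chemokines of the activated endothelium. SELE (E-selectin, ENSG00000007908, minus strand of chromosome 1 from 169722640 to 169764705, GRCh38), which captures rolling leukocytes, rose from 5.13 ± 0.70 CPM (SD, n = 3) to 3592 ± 184 CPM (SD, n = 2), a log2 fold change of 9.45 ± 0.09 (SE, edgeR adjusted p = 1.53e-17). VCAM1, a ligand of leukocyte integrins, rose from 9.99 ± 0.58 to 648 ± 44.7 CPM, a log2 fold change of 6.02 ± 0.07 (SE, edgeR adjusted p = 1.1e-16). ICAM1 rose by 3.78 ± 0.09, and the chemokines CXCL8 and CCL2 rose by 7.37 ± 0.10 and 3.70 ± 0.09 on the log2 scale. NOS3, the endothelial nitric oxide synthase, fell from 51.9 ± 3.69 to 11.4 ± 0.54 CPM, a log2 fold change of −2.19 ± 0.12. The flow-responsive factor KLF2 rose from 7.39 ± 0.26 to 27.4 ± 0.69 CPM.

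Of 17395 genes tested, 3804 rose and 3793 fell with TNF against untreated cells, 1532 and 1087 of them by a log2 fold change of 1 or more. Among genes that met the naming rule, the largest rises included UBD, a ubiquitin-like modifier, at 10.89 ± 0.14, and OR2I1P at 9.90 ± 0.20. UBD and OR2I1P overlap each other and are uncertain. CSF2, the cytokine GM-CSF, went from 2 counts over all untreated libraries to 73.9 ± 1.30 CPM, a ratio of 2501 (95% counting interval 692 to 20661). SGPP2 had 3 counts in untreated cells and a ratio of 805 (275 to 3908). ANO9 had 0 counts in untreated cells and 54.5 ± 5.44 CPM with TNF, at least 1226-fold higher with 3 counts taken as the floor over the group. Among the same genes, the largest falls were those of AQP1, CD36 and INHBB. The water channel AQP1 went from 299.5 ± 15.1 to 1.33 ± 0.16 CPM. The fatty acid receptor CD36 went from 6.81 ± 3.09 to 0.083 ± 0.12 CPM, and INHBB from 5.96 ± 0.30 to 0.087 ± 0.12 CPM. Some of these folds depended on single libraries. The untreated counts of CSF2 lay in replicate 2 only and those of SGPP2 in replicate 1 only. UBD was at 11.65 without untreated replicate 2 and OR2I1P at 11.66 without untreated replicate 1. CD36 had 0 counts in TNF replicate 1 and INHBB in TNF replicate 2, without which they were at −5.29 and −5.03, and without the other TNF library their TNF counts were all 0. CCL23 fell by 5.90, P-selectin (SELP) by 5.67 and MMP28, which overlaps TAF15 and is uncertain, by 5.24 on the log2 scale.

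**Figure D1:**
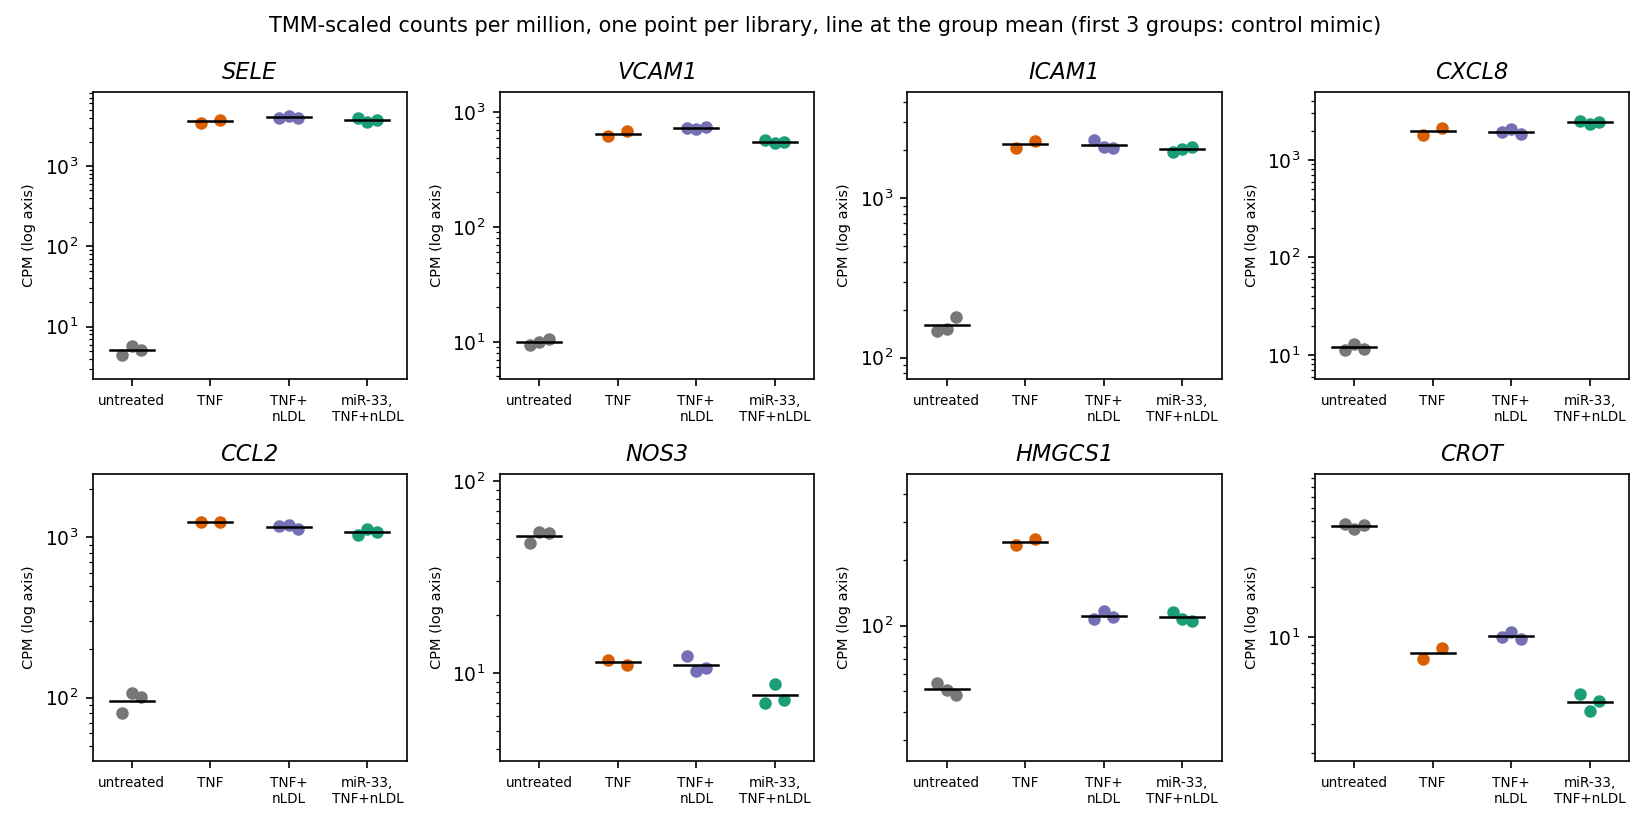
TMM-scaled CPM on a log axis of SELE, VCAM1, ICAM1, CXCL8, CCL2, NOS3, HMGCS1 and CROT in the 4 groups, with a point per library and a line at the group mean. SELE lies near 5.13 CPM in untreated cells and near 3592 CPM with TNF, and CROT is lowest with the miR-33 mimic at 4.10 CPM.

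Inflammatory lists rose together. In the NF-kB list 27 of 28 members rose and 0 fell, with the same counts adjusted over the list alone, a median log2 fold change of 2.03 and a camera adjusted p = 4.56e-04 with an estimated correlation. TNIP3 and TRAF1, which restrain or relay TNF signals, rose by 7.23 ± 0.18 and 6.35 ± 0.11. Of 32 chemokines and cytokines 27 rose and 2 fell, also adjusted over the list alone (median 4.93, adjusted p = 4.56e-04 with an estimated correlation), and IL1B had 1 count in untreated cells, in replicate 2, and a ratio of 799 (143 to 31609). Of 39 interferon response genes 38 rose, 39 adjusted over the list alone (median 2.57, adjusted p = 0.0111 with an estimated correlation). Among them MX2 rose by 5.65 ± 0.16 and CMPK2, which overlaps RSAD2, by 5.30 ± 0.17. All 17 members of the MHC class I list rose, also adjusted over the list alone (median 1.66, adjusted p = 0.0316 with an estimated correlation). HLA-F was at 3.23 and the peptide transporter TAP1 at 2.37. The adhesion list had 9 rises and 4 falls in 17, also adjusted over the list alone (median 1.14, adjusted p = 0.0133 with an estimated correlation).

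Sterol synthesis and cell cycle genes also rose. In the cholesterol list 21 of 24 members rose and 2 fell, 22 and 2 adjusted over the list alone (median 1.06, adjusted p = 0.0133 with an estimated correlation). HMGCS1, an early enzyme of sterol synthesis, rose by 2.25 ± 0.07 and INSIG1, which restrains SREBP activation, by 1.95 ± 0.06. SREBF2 and SREBF1, the transcription factors of these pathways, rose by 0.61 ± 0.07 and 1.04 ± 0.08, SREBF1 overlapping RAI1. All 40 cell cycle genes rose, also adjusted over the list alone (median 1.27, adjusted p = 0.0451 with an estimated correlation). E2F1 was at 2.21 and CCNE2, which overlaps INTS8 and NDUFAF6, at 2.23. The fatty acid synthesis list had 11 rises and 2 falls in 17, also adjusted over the list alone (median 0.84). Its call was lost at adjusted p = 0.146 with an estimated correlation. ACSL3 was at 1.66 and PNPLA3, which overlaps SAMM50, at 2.58. The unfolded protein response list had 21 rises and 2 falls in 26, also adjusted over the list alone (median 0.46). Its call was lost at adjusted p = 0.359 with an estimated correlation. ATF3 was at 2.14 and ASNS at 1.47.

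Other lists fell or were mixed. In the fatty acid oxidation list 0 of 25 members rose and 13 fell, also adjusted over the list alone (median −0.27), and the call was lost at adjusted p = 0.0975 with an estimated correlation. Its largest falls were PDK4 at −4.27 ± 0.15 and CROT, a peroxisomal acyl transferase, at −2.54 ± 0.11, and CPT1A fell by 1.13 ± 0.07 on the log2 scale. Lymphatic endothelial markers had 4 falls in 5, also adjusted over the list alone (median −1.73, adjusted p = 0.0133 with an estimated correlation), with MMRN1 at −2.26 and LYVE1 at −2.11. Mitochondrially encoded mRNAs had 10 falls in 13, 11 adjusted over the list alone (median −0.27), with MT-CO1 at −0.42 and MT-CYB at −0.35 and no set call (camera adjusted p = 0.0815 at the preset correlation). Endothelial identity genes had 8 rises and 17 falls in 32, also adjusted over the list alone (median −0.30, camera adjusted p = 0.0815 at the preset correlation), with HEY1 at 4.32 and KLF4 at 2.25 the largest changes. The efflux list had 5 rises and 5 falls in 17, 5 and 6 adjusted over the list alone. Its median was 0.01, its mean −0.28 and its camera direction up (camera adjusted p = 0.882 at the preset correlation). Within it the cholesterol exporter ABCA1 was at −1.49 ± 0.13 and OSBPL6 at −2.86 ± 0.25, both called falls, whereas ABCG1 rose by 0.79 ± 0.08 and NPC1, which overlaps RMC1, by 1.80 ± 0.07.

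No set call was made for 6 further lists. Reported miR-33 targets had 10 rises and 11 falls in 28 (median −0.12, camera adjusted p = 0.371 at the preset correlation), mesenchymal transition genes 5 and 8 in 25 (median −0.23, 0.111), and autophagy genes 10 and 4 in 30 (median 0.06, 0.174), each with the same counts adjusted over the list alone. In them POSTN was at −3.54 and TFEB, at −1.30, was no longer called without TNF replicate 1 (adjusted p = 0.114), TNF replicate 2 (0.159), untreated replicate 2 (0.0698) or untreated replicate 3 (0.0784). Against a fold change of 1.2 neither TFEB nor MT-CYB was called. Coagulation genes had 6 rises and 9 falls in 18, 8 and 9 adjusted over the list alone (median −0.10, mean 0.16, camera adjusted p = 0.569 at the preset correlation), with tissue factor F3 at 2.52. Smooth muscle markers had 0 rises and 1 fall in 6, also adjusted over the list alone (median 0.07, mean 0.03, camera direction down, camera adjusted p = 0.622 at the preset correlation). Fibroblast markers had 3 rises and 3 falls in 11, also adjusted over the list alone (median 0.03, camera adjusted p = 0.334 at the preset correlation), with PDGFRA at 3.73, and THY1 at 0.55 ± 0.16 CPM with TNF against 2 counts over all untreated libraries. Of the 4 leukocyte markers measured, CD68, which overlaps an unnamed locus on its strand, rose by 2.07 and CD14 fell by 3.45 on the log2 scale.

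Adding nLDL to TNF lowered genes of sterol and fatty acid synthesis. HMGCS1 (ENSG00000112972, minus strand of chromosome 5 from 43287470 to 43313512) fell from 242 ± 9.37 CPM (SD, n = 2) to 111 ± 4.84 CPM (SD, n = 3), a log2 fold change of −1.12 ± 0.07 (SE, edgeR adjusted p = 2.84e-06). MSMO1, which demethylates sterols, fell by 1.02 ± 0.07 and EBP, a sterol isomerase, by 1.02 ± 0.12. FASN, the fatty acid synthase, fell by 0.93 ± 0.10 and ELOVL6, which lengthens its product, by 0.98 ± 0.09. The chemokine CXCL6 rose from 416 ± 37.4 to 663 ± 26.7 CPM, a log2 fold change of 0.67 ± 0.08 (SE, edgeR adjusted p = 6.94e-04).

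In all 33 genes rose and 69 fell, 2 and 6 of them by a log2 fold change of 1 or more. Rises of that size were 4 without untreated replicate 1 and 1 without TNF replicate 1 or any TNF with nLDL replicate, and falls were 3 without TNF replicate 2. The total counts depended on single libraries. They were 134 and 145 without untreated replicate 1, 5 and 23 without TNF replicate 1, 16 and 26 without TNF replicate 2, 12 and 47, 14 and 36, and 14 and 39 without TNF with nLDL replicates 1, 2 and 3, and 17 and 52 without miR-33 mimic replicate 3. Scaled by library size only, 21 rose and 112 fell. The other large falls were MVD at −1.03 and ACAT2 at −1.19, which overlaps SOD2 and TCP1 and is uncertain. The other large rises were CPED1 at 1.41, PDK4 at 1.14, C3, which overlaps GPR108, at 0.79, ADAMTS18 at 0.74 and GALNT15 at 0.72, and CXCL5 rose by 0.52. Without TNF replicate 1 the calls of CPED1 (adjusted p = 0.250), ADAMTS18 (0.137), CXCL5 (0.164), C3 (0.0790), GALNT15 (0.0794) and MVD (0.0685) were lost. Without TNF replicate 2 those of ADAMTS18 (0.115) and PDK4 (0.0639) were lost, and CPED1 was lost without each of TNF with nLDL replicates 1, 2 and 3 (0.0675, 0.0521 and 0.0678). Against a fold change of 1.2 CPED1, ADAMTS18 and CXCL5 were not called.

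In the cholesterol list 0 of 24 members rose and 18 fell, 0 and 21 adjusted over the list alone (median −0.75, adjusted p = 3.63e-05 with an estimated correlation). In the fatty acid synthesis list 0 of 17 rose and 9 fell, 0 and 11 adjusted over the list alone (median −0.32, adjusted p = 0.00132 with an estimated correlation). Lymphatic markers had 0 calls in 5, and 3 rises adjusted over the list alone (median 0.36, adjusted p = 0.0271 with an estimated correlation). SREBF1 at −0.28 ± 0.08 (edgeR adjusted p = 0.207) and SREBF2 at −0.26 ± 0.07 (0.140) did not pass the test. Neither did ABCA1 at 0.35, ABCG1 at 0.02, CPT1A at 0.05, CROT at 0.35, VCAM1 at 0.17, ICAM1 at −0.01, SELE at 0.16, CCL2 at −0.10, CXCL8 at −0.02, KLF2 at −0.0033 or NOS3 at −0.04.

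**Figure D2:**
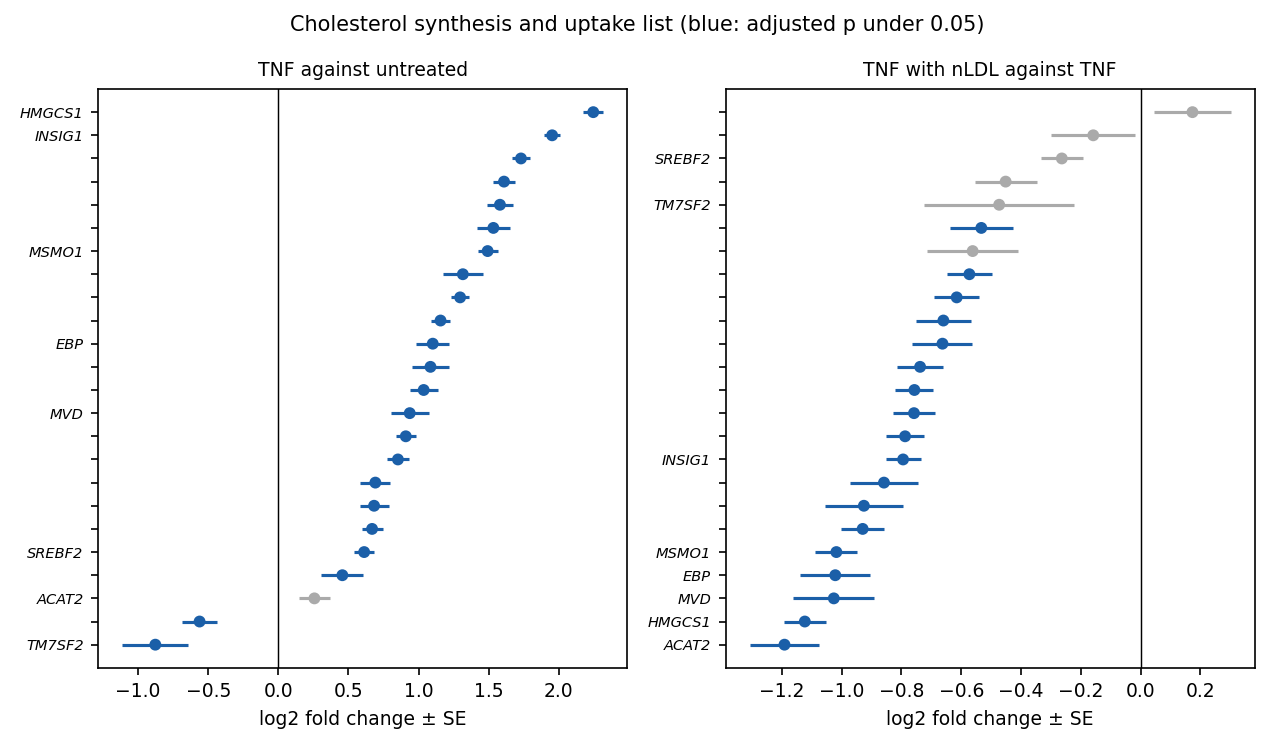
Log2 fold change ± SE of the 24 measured genes of the cholesterol list in TNF against untreated and in TNF with nLDL against TNF, with blue points for genes with an adjusted p under 0.05 and symbols beside genes named in the text. With TNF 21 genes lie above 0 as calls, and with nLDL added 18 lie below 0 as calls; the 2 panels share the TNF libraries, so that opposite signs are partly built in.

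The remaining lists moved little with nLDL. Chemokines had 3 rises and 0 falls in 32, 9 and 3 adjusted over the list alone (median 0.17), and the call was lost at adjusted p = 0.220 with an estimated correlation. The NF-kB list had 1 rise and 0 falls in 28, also adjusted over the list alone (median 0.10). The call was lost at adjusted p = 0.457 with an estimated correlation, and also without TNF replicate 1 (median 0.04) or TNF with nLDL replicates 1 (0.07) or 2 (0.08). The interferon list had 0 calls in 39, also adjusted over the list alone (median 0.07). Its set call was lost at adjusted p = 0.733 with an estimated correlation, and without TNF replicate 1 (median −0.0446) or TNF with nLDL replicates 1 (0.03) or 2 (0.04). The cell cycle list had 0 calls in 40, 0 rises and 2 falls adjusted over the list alone (median −0.10). Its set call was lost at adjusted p = 0.577 with an estimated correlation, and without TNF replicate 1 (median −0.06). No set call was made for the others, whose rises and falls over all genes tested, and then adjusted over the list alone, were 0 and 2, then 3 and 2 for adhesion (median 2.3e-04, mean 0.03, camera direction down), and 0 and 1, then 0 and 3 for efflux. They were 1 and 0 both ways for fatty acid oxidation, 1 and 0, then 1 and 2 for reported miR-33 targets, 0 and 1, then 4 and 2 for endothelial identity, and 0 and 0, then 0 and 3 for mesenchymal transition. They were 0 and 0, then 0 and 1 for autophagy (median 0.01, mean −0.01, camera direction down), 0 and 0, then 1 and 3 for the unfolded protein response (median 0.02, mean −0.05, camera direction down), and 1 and 0, then 2 and 2 for coagulation (median −0.03, camera direction up). MHC class I, smooth muscle (median 0.08, camera direction down), fibroblast and mitochondrial lists had 0 and 0 both ways.

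TNF with nLDL against untreated cells shared libraries with both comparisons above and is given for its values only. SELE was higher by 9.61 ± 0.09, VCAM1 by 6.19 ± 0.07, CXCL8 by 7.35 ± 0.09, ICAM1 by 3.76 ± 0.08 and CCL2 by 3.60 ± 0.09 on the log2 scale, and NOS3 was lower at −2.23 ± 0.10. In all 4160 genes rose and 4367 fell, 1603 and 1166 by a log2 fold change of 1 or more. Scaled by library size only, 3389 rose and 5399 fell, with the median of all genes at −0.12. Among genes that met the naming rule, the largest rises included ANO9 (at least 1004-fold) and HSD11B1 (5.51 ± 1.22 CPM), both with 0 counts in untreated cells. UBD and OR2I1P, which overlap each other, were at 11.21 and 10.28, and TNFAIP6 was at 9.99. CSF2 had 2 counts in untreated cells and a ratio of 2240.1 (95% counting interval 619.8 to 18503). UBD was at 11.97 without untreated replicate 2 and OR2I1P at 12.04 without untreated replicate 1. The largest falls among genes that met the naming rule were AQP1 at −7.97, INHBB at −6.25, CD36 at −6.19, CCL23 at −5.74, MMP28, which overlaps TAF15, at −5.59 and PLXNA4 at −4.95. With near 0 counts under stimulus, CD36 was at −7.99 without TNF with nLDL replicate 3 and INHBB at −6.86 without TNF with nLDL replicate 1. Among genes of lipid control, SREBF1 was at 0.76, SREBF2 at 0.35, ABCG1 at 0.80, ABCA1 at −1.14, CPT1A at −1.08 and CROT at −2.19, all called, as was KLF2 at 1.89. SREBF2 was not called against a fold change of 1.2.

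The lists called here with an estimated correlation were chemokines (27 rises, 2 falls, median 5.08, adjusted p = 3.30e-04), NF-kB (27 and 0, median 2.01, adjusted p = 3.30e-04), interferon response (39 and 0, median 2.72, adjusted p = 0.00989), MHC class I (17 and 0, median 1.72, adjusted p = 0.0312), adhesion (10 and 5, median 0.94, adjusted p = 0.0208) and lymphatic markers (1 and 4, median −1.62, adjusted p = 0.0312). Adjusted over the list alone these counts were the same, except 28 and 0 for NF-kB. CSF3 was at 9.42, TNIP3 at 7.52, TRAF1 at 6.15, MX2 at 5.79, CMPK2 at 5.29, HLA-F at 3.32, TAP1 at 2.37, FLT4 at −1.85 and LYVE1 at −1.75. Calls lost with an estimated correlation were those of cholesterol (12 and 3, then 13 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.344 with an estimated correlation), fatty acid oxidation (1 and 12 both ways, median −0.21, adjusted p = 0.106), cell cycle (39 and 0, then 40 and 0, median 1.24, adjusted p = 0.0724) and the unfolded protein response (19 and 2 both ways, median 0.42, adjusted p = 0.389). Endothelial identity (9 and 19 both ways, median −0.29, adjusted p = 0.467 with an estimated correlation) also lost its call without TNF replicates 1 or 2, TNF with nLDL replicates 2 or 3, or miR-33 mimic replicate 3. Mesenchymal transition (6 and 11 both ways, median −0.32, adjusted p = 0.167 with an estimated correlation) lost it without TNF with nLDL replicates 2 or 3. In these lists INSIG1 was at 1.16, TM7SF2, which overlaps VPS51, at −1.35, PDK4 at −3.14, CENPE at 2.10, CCNE2 at 2.16, ATF3 at 1.79, ASNS at 0.92, HEY1 at 4.66, KLF4 at 2.27 and POSTN at −3.15.

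Mitochondrially encoded mRNAs had 0 rises and 11 falls, 0 and 12 adjusted over the list alone (median −0.29, camera adjusted p = 0.0541 at the preset correlation), with MT-CO1 at −0.43 and MT-CYB at −0.41. No set call was made for efflux (5 and 7), fatty acid synthesis (8 and 4, median 0.09), reported miR-33 targets (9 and 12, then 9 and 13 adjusted over the list alone), autophagy (11 and 6, then 12 and 8), coagulation (7 and 9, median −0.25, mean 0.13), smooth muscle (2 and 3, median −0.02, mean 0.15) or fibroblast markers (4 and 4, median −0.16, mean 0.47, camera direction up). Their strongest members were OSBPL6 at −2.69, NR1H3, which overlaps ACP2, at −1.62, ACSL3 at 1.51, PNPLA3 at 1.41, NPC1 at 1.49, F3 at 2.33, MYH11, which overlaps NDE1, at 1.89, TAGLN, which overlaps PCSK7, at −0.95, PDGFRA at 3.69, LUM at 3.46, and TFEB at −1.25. Without untreated replicate 1 LUM was at 4.79 and MYH11 at 3.80. MYH11 was no longer called without TNF with nLDL replicate 3 (adjusted p = 0.104) or untreated replicates 2 (0.101) or 3 (0.108), nor TFEB without untreated replicate 3 (0.0541). Of leukocyte markers, CD68, which overlaps that unnamed locus, was at 2.31 and CD14 at −1.53.

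The miR-33 mimic, compared with the control mimic under TNF with nLDL, lowered reported miR-33 targets, among them genes of fatty acid oxidation. CROT (ENSG00000005469, plus strand of chromosome 7 from 87345664 to 87399794), a reported miR-33 target, fell from 10.2 ± 0.52 CPM to 4.10 ± 0.49 CPM (SD, n = 3 each), a log2 fold change of −1.32 ± 0.11 (SE, edgeR adjusted p = 2.52e-05). HADHB, a subunit of the mitochondrial trifunctional protein, fell from 130 ± 3.78 to 79.6 ± 5.41 CPM, a log2 fold change of −0.70 ± 0.06 (SE, edgeR adjusted p = 4.44e-05). HADHB overlaps HADHA, which was at −0.03. The cholesterol exporter ABCA1 fell by 0.62 ± 0.12 and CPT1A by 0.33 ± 0.06 on the log2 scale. The adhesion molecule VCAM1 fell from 730 ± 16.1 to 553 ± 14.5 CPM, a log2 fold change of −0.40 ± 0.05 (SE, edgeR adjusted p = 9.45e-04), whereas CXCL6 rose from 663 ± 26.7 to 1263 ± 50.8 CPM.

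In all 144 genes rose and 233 fell, 9 and 18 of them by a log2 fold change of 1 or more, and 2154 genes had an unadjusted p under the threshold. Rises of that size were 4 without TNF with nLDL replicate 2, and 3, 5 and 5 without miR-33 mimic replicates 1, 2 and 3. The total counts were 280 and 394 without untreated replicate 1, and 75 and 123, 62 and 150, and 50 and 145 without TNF with nLDL replicates 1, 2 and 3. They were 79 and 139, and 56 and 134, without miR-33 mimic replicates 1 and 2, and without replicate 3 there were 67 rises among 194 calls. DESeq2 called 463 genes and limma-voom 400, and 346 were called by edgeR and both. The falls and rises named next were the largest among genes that met the naming rule. Other called genes changed more, by up to 5.97 on the log2 scale. The falls were CCL8 at −1.56 ± 0.12, SEMA7A at −1.39 ± 0.18, CROT, the alarmin IL33 at −1.10 ± 0.16, the prostaglandin transporter SLCO2A1 at −1.08 ± 0.13 and ZNF366 at −1.06 ± 0.18. The rises were RELN at 1.29 ± 0.18, SULT1B1 at 1.11 ± 0.16, SEMA3C at 0.99 ± 0.21, CBLN2 at 0.98 ± 0.17, SERPINB2 at 0.95 ± 0.16 and CXCL6 at 0.93 ± 0.07. SEMA3C lost its call without each of the 6 compared libraries, at an adjusted p of 0.0713 to 0.123. Against a fold change of 1.2, the calls of VCAM1, ABCA1, CPT1A, NOS3, CXCL8, THBD, F2RL1, CBLN2, SEMA3C, ALCAM, PLK1, BUB1B and TGFBI with the mimic were lost.

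The list of reported miR-33 targets fell as a set. Of 28 members 0 rose and 5 fell, 0 and 8 adjusted over the list alone (median −0.17, adjusted p = 0.00738 with an estimated correlation). In the fatty acid oxidation list 0 of 25 rose and 5 fell, also adjusted over the list alone (median −0.07, adjusted p = 0.0383 with an estimated correlation). The 5 were CROT, HADHB, CPT1A, PDK4 at −0.57 and PPARA at −0.33, the last pair chosen for naming after their values were seen. The 4 other than PPARA are members of both lists. In a test added after seeing the data, without these 4 the targets kept their call (median −0.15, adjusted p = 0.0383 with an estimated correlation). The fatty acid oxidation list lost it (median −0.06, adjusted p = 0.606 with an estimated correlation). PDK4 lost its call without 7 of the 11 libraries in turn and PPARA without 8, at adjusted p up to 0.187 and 0.204. ABCA1 lost its call without TNF with nLDL replicate 1 (adjusted p = 0.0554) or miR-33 mimic replicate 3 (0.0597), and CPT1A without TNF with nLDL replicate 1 (0.0636) or miR-33 mimic replicate 1 (0.0664). The efflux list had 0 rises and 2 falls in 17, also adjusted over the list alone (median −0.10), with no set call (camera adjusted p = 0.0578 at the preset correlation). SREBF1 at −0.05, SREBF2 at −0.19 and ABCG1 at −0.10 did not pass the test, and the cholesterol list had 0 calls in 24, also adjusted over the list alone (median 0.02).

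**Figure D3:**
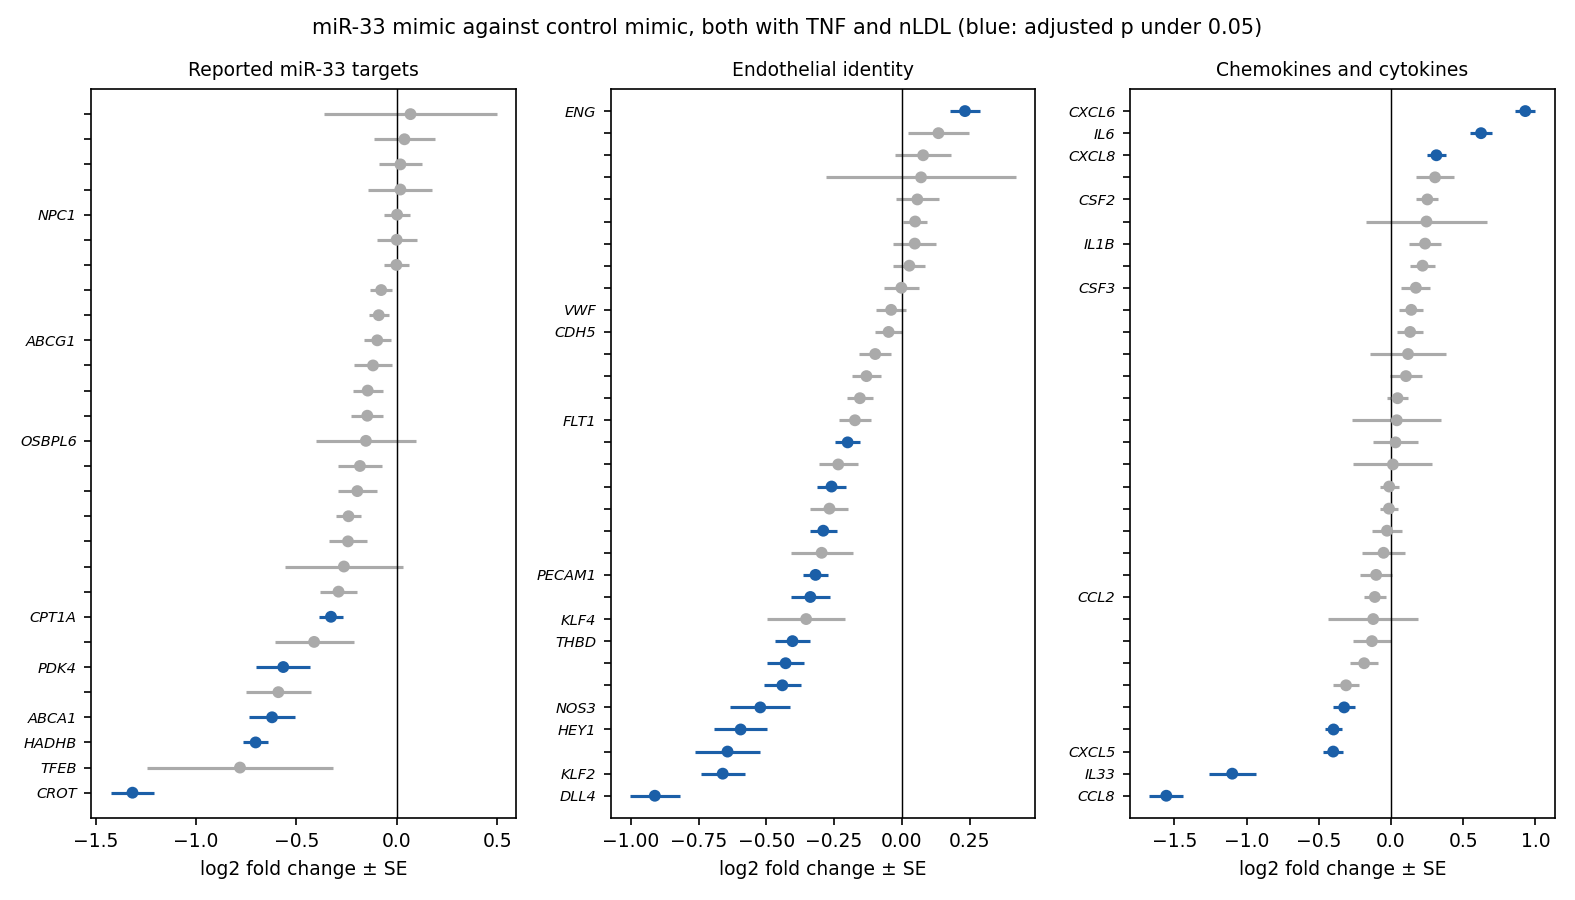
Log2 fold change ± SE, miR-33 mimic against control mimic under TNF with nLDL, of the measured members of the lists of reported miR-33 targets, endothelial identity and chemokines and cytokines, with blue points for genes with an adjusted p under 0.05 and symbols beside genes named in the text. CROT is the lowest of the targets at −1.32, and 13 of 32 endothelial identity genes lie below 0 as calls.

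Endothelial identity genes were lower with the mimic. In the list 1 of 32 rose and 13 fell, 1 and 20 adjusted over the list alone (median −0.22, adjusted p = 0.0219 with an estimated correlation). The Notch ligand DLL4 fell from 18.0 ± 1.01 to 9.55 ± 0.88 CPM, a log2 fold change of −0.91 ± 0.09, and KLF2 from 27.4 ± 2.42 to 17.3 ± 0.85 CPM, a log2 fold change of −0.66 ± 0.08. NOS3 fell by 0.52 ± 0.11, a call lost without TNF with nLDL replicates 1 (adjusted p = 0.121) or 3 (0.0598) or miR-33 mimic replicates 1 (0.121) or 3 (0.108). ENG, the only member that rose in this fit, was at 0.23, and was named after its value was seen. Lymphatic markers had 1 rise, RELN, and 2 falls in 5, also adjusted over the list alone (median −0.21). LYVE1 was at −0.86, and the set call was lost at adjusted p = 0.0675 with an estimated correlation. Mesenchymal transition genes had 4 rises and 1 fall in 25, 6 and 1 adjusted over the list alone (median 0.06). CDH2 was at 0.68 and TGFBI at 0.73, and the set call was lost at adjusted p = 0.0801 with an estimated correlation. TGFBI lost its call with limma-voom, and also without 8 of the 11 libraries in turn, then at adjusted p from 0.0607 to 0.147.

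Cell cycle genes were higher with the mimic, with 10 rises and 0 falls in 40, and 33 and 0 adjusted over the list alone (median 0.35, adjusted p = 0.0383 with an estimated correlation). PLK1 rose by 0.51 ± 0.09 and BUB1B by 0.49 ± 0.11. PLK1 lost its call without TNF with nLDL replicate 3 (adjusted p = 0.0526) or miR-33 mimic replicate 2 (0.0516), and BUB1B without each of the 6 compared libraries (0.0604 to 0.143). The labels give no measure of cell density at harvest. An effect of the mimic itself and a difference in density between cultures were not told apart.

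Inflammatory genes went both ways with the mimic. Of 32 chemokines and cytokines 3 rose and 5 fell, 4 and 6 adjusted over the list alone (median 0.02, mean −0.03), with no set call (camera adjusted p = 0.714 at the preset correlation). CXCL8 rose from 1946 ± 110.2 to 2419.7 ± 95.6 CPM, a log2 fold change of 0.31 ± 0.07 (SE, edgeR adjusted p = 0.0256), and lost its call without TNF with nLDL replicates 1 (0.103) or 3 (0.143) or miR-33 mimic replicates 1 (0.103), 2 (0.0547) or 3 (0.119). SELE at −0.10, ICAM1 at −0.09 and CCL2 at −0.11 did not pass the test. The adhesion list had 2 rises and 3 falls in 17, 2 and 6 adjusted over the list alone (median −0.11). CD34 was at −0.55 and ALCAM at 0.48, and the set call was lost at adjusted p = 0.163 with an estimated correlation. ALCAM lost its call without TNF with nLDL replicates 1 (adjusted p = 0.0736) or 3 (0.0883) or miR-33 mimic replicates 2 (0.0516) or 3 (0.0597). The interferon list had 0 calls in 39, also adjusted over the list alone (median −0.05), and its set call was lost at adjusted p = 0.750 with an estimated correlation, and without untreated replicate 2, TNF with nLDL replicates 1 or 2 or miR-33 mimic replicates 1 or 2. NF-kB (median −0.01) and MHC class I genes (median −0.07) had 0 calls, also adjusted over the list alone, and no set call.

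Among the remaining lists, autophagy had 0 rises and 2 falls in 30, 0 and 4 adjusted over the list alone (median −0.09), and its call was lost at adjusted p = 0.399 with an estimated correlation. Mitochondrially encoded mRNAs had 0 calls in 13, also adjusted over the list alone (median 0.09), and the set call was lost at adjusted p = 0.654 with an estimated correlation, and without TNF with nLDL replicate 1 (median 0.05). Coagulation genes had 1 rise and 2 falls in 18, 2 and 3 adjusted over the list alone (median 0.05), with the protease-activated receptor F2RL1 at 0.50 and THBD at −0.40. Fatty acid synthesis had 0 calls, 1 rise adjusted over the list alone (median 0.06), the unfolded protein response 0 calls, 1 rise and 2 falls adjusted over the list alone (median 0.01, mean −0.02, camera direction up), and smooth muscle (median −0.07) and fibroblast markers (median 0.12) 0 calls both ways.

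Genes that had responded to TNF were called more often with the mimic than other genes. Of the 1532 genes that rose with TNF, 54 rose and 46 fell with the mimic (6.53% called), and of the 1087 that fell with TNF, 17 rose and 69 fell (7.91% called), against 1.29% of other genes. The genes that fell with TNF had a median of −0.07 with the mimic. Their set call (camera adjusted p = 5.91e-04 at the preset correlation) was lost at adjusted p = 0.0602 with an estimated correlation. For the genes that rose with TNF no shift as a set was called (limma camera, adjusted p = 0.196). Across the 17395 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of 0.0111.

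Genes with a miR-33 site in the 3′ UTR were lower with the mimic than genes without it. The site CAATGCA was present in 1209 of 12824 genes, and the mean difference after regression was −0.042 on the log2 scale, lower than for all 6302 other 7-mers of similar frequency. The site was present in 40 of 229 genes that fell with the mimic (17.5%), 12 of 136 that rose (8.82%) and 9.43% of all genes. These shares were not adjusted for UTR length or GC content, and before regression the mean difference was −0.028. With TNF against untreated 1201 of the 6302 other 7-mers were as low, and with nLDL added to TNF 5681. The site of cel-miR-67, a worm microRNA often used as a control mimic, GGTTGTG, was at −0.0060, with 1279 of 6898 other 7-mers as low, and the labels do not say which control was used. Without adjustment, GGTTGTG was present in 30 of 229 genes that fell with the mimic (13.1%), 16 of 136 that rose (11.8%) and 10.3% of all genes.

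**Figure D4:**
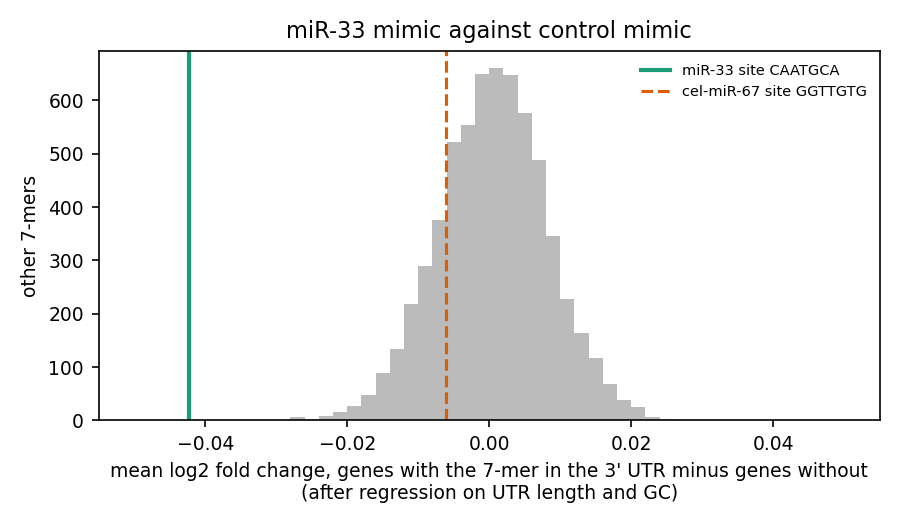
Histogram over other 7-mers of the mean log2 fold change of genes with the 7-mer in the 3′ UTR minus genes without it, miR-33 mimic against control mimic, with lines at the miR-33 site CAATGCA and at the cel-miR-67 site GGTTGTG. The miR-33 site lies at −0.042, below all 6302 other 7-mers of similar frequency.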

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

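Leaving out the chromosome 21 locus, leaving out members that a pair of lists share, and the site effect under fits other than the 8-base site, were tests chosen after seeing the data. Over 14 leading results and 306 values under alternatives, 259 were the same, 32 weaker, 14 stronger and 1 reversed. For a test, the same means an unchanged sign and side of the threshold. For a count of genes or lists, it means only a value within 1.5-fold of the main one. Of 176 results for named genes 143 were the same under all alternatives, as were 17 of 37 for lists and 6 of 12 for other counts. Of called results a single value reversed, the interferon list in TNF with nLDL against TNF without TNF replicate 1, at −0.0446, where leaving out single libraries gave medians up to 0.180. Results that had not passed the test also changed sign. Leaving out single libraries gave, for nLDL on TNF, ABCG1 from −0.0114 to 0.0619, ICAM1 from −0.0829 to 0.0596, CXCL8 from −0.131 to 0.106, KLF2 from −0.0686 to 0.0595 and NOS3 from −0.123 to 0.0163, and for the mimic SREBF1 from −0.0947 to 0.00118. For nLDL on TNF, ABCG1 was at −0.0326 and CPT1A at −1.45e-04 scaled by library size only, and ABCG1 at −0.0130 and KLF2 at 0.0160 with the replicate number as a block. Tested against a fold change of 1.2, falls with TNF were 2516, rises and falls with nLDL on TNF 5 and 22, falls with TNF with nLDL against untreated 2897, and rises and falls with the mimic 20 and 40. For nLDL on TNF the rises and falls were 87 and 107 with DESeq2 and its own filter, 79 and 105 without that filter, 139 and 153 in a fit of the 2 groups only, and 21 and 112 scaled by library size only. Rises there were 50 with limma-voom and 60 without a filter on low counts. In a fit of the 2 groups only the mimic raised 301 genes. Leaving out single libraries gave 5 to 134 rises and 23 to 145 falls for nLDL on TNF, and 50 to 280 rises and 123 to 394 falls for the mimic; the cause of these shifts was not tested. With no fold threshold the genes that fell with TNF had a median of −0.0189 with the mimic and were no longer called, and with a log2 threshold of 2 it was −0.153. The genes that rose with TNF, not called either way, went from 0.0175 to −0.0263 at that threshold. With the replicate number as a block the rises and falls were 3614 and 3615 for TNF, 19 and 44 for nLDL on TNF, 4128 and 4228 for TNF with nLDL against untreated, and 117 and 195 for the mimic. The numbers showed no pairing of the libraries: over 15 pairs of the same number the correlation of deviations ran from −0.141 to 0.165, and 5 of 11 libraries correlated best with their own number. Numbers are those of the sample titles, and the column name of TNF with nLDL replicate 3 carries a different number. The site effect lay between −0.0472 and −0.0368 under the alternatives, and at −0.046 for the 8-base site, with 35 of 22055 8-mers as low. Genes below the floor of 3 counts (0.115 to 0.147 CPM) could not be told from absent at this depth.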

Other observations

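Genes in this paragraph were chosen after their values were seen, from the comparison of the miR-33 mimic with the control mimic under TNF with nLDL. EFNB2, an arterial ephrin, fell from 159.5 ± 11.9 to 96.0 ± 2.67 CPM (SD, n = 3 each), a log2 fold change of −0.73 (edgeR adjusted p = 2.52e-05), the Notch effectors HES1 and HEY1 fell by 0.76 and 0.59 on the log2 scale, and the apelin receptor APLNR fell by 1.88. ACKR1, a venular receptor that carries chemokines across the endothelium, fell from 45.6 ± 4.30 to 25.8 ± 1.01 CPM. SOCS3, a brake on cytokine signalling, fell by 0.68, IGFBP5 by 2.33 and the protease inhibitor TIMP3 by 0.98. The limit of 5 CPM was not applied in this paragraph. APLNR and IGFBP5 fell by more than the largest fall that met the naming rule, and did not meet that rule themselves. AQP1 fell by 1.49 at a low level, with libraries at 1.01 to 1.34 CPM with the control mimic and 0.371 to 0.461 CPM with the miR-33 mimic. IL6, which overlaps STEAP1B, rose from 109.7 ± 7.36 to 169 ± 12.2 CPM, a log2 fold change of 0.62 (edgeR adjusted p = 7.03e-04), PTX3 rose by 0.50, the prostaglandin synthase PTGS2 by 0.59, the IL33 receptor IL1RL1, which overlaps IL18R1, by 0.67, NOX4 by 0.51 and CLDN11 by 0.62. These calls were kept with each of the 11 libraries left out in turn.

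The 7-mer with the largest z among rises with TNF was TATTTAT, the core of AU-rich elements that control mRNA decay. It was present in 4643 genes, which were higher than genes without it by 0.11 on the log2 scale after regression (z = 5.18 over 15967 7-mers, chosen after the ranking was seen).

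Of the tests that follow, the ratio of PECAM1 to CDH5 and VWF and, for the genes raised by TNF, library-size scaling and leaving out untreated replicate 1 were chosen after the result was seen. The endothelial identity list was lower with the mimic. A lower share of endothelial cells would lower their markers alike, but PECAM1 lay −0.27 ± 0.060 (SE) from the mean of CDH5 and VWF on the log2 scale, which were at −0.05 and −0.04. This form replaced an earlier one, which required PECAM1 and CDH5 near 0 or smooth muscle and fibroblast medians of opposite sign and which PECAM1 did not meet. The present form was written with these values known, and its SE takes the genes as independent. No conclusion on the share of endothelial cells is drawn from it. Without members that hold a miR-33 site, of which FLT1 was the only one, the median was −0.23, and after trends in transcript length and GC content were removed it was −0.21, so neither accounts for the list as a whole. What lies behind the lower list stays open.

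TNF raised cholesterol synthesis and cell cycle lists. With library size as the only scaling the lower of the 2 medians was 1.01, without untreated replicate 1 it was 1.04, and after trends in length and GC content were removed it was 0.96. The scaling, that library and those trends therefore do not account for the rises. An effect of TNF itself and a difference in cell density between cultures, for which the labels give no measure, were not told apart and stay open.

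Genes called with the mimic were concentrated among genes that respond to TNF, at 7.11% of 2617. Some genes not reported here were left out of these shares. Other genes matched on mean expression were called at 1.22% (1.06 to 1.40 over 1000 resamples), so higher expression does not account for the excess. Among genes without the 7-base miR-33 site the shares were 8.35% and 1.62%, a ratio of 5.15. Sites of that kind in the UTRs searched therefore do not account for the excess either. Shorter sites and sites outside those UTRs were not searched. The 2 comparisons also share the spread estimated for each gene in the common fit, so their calls are not independent. The matching did not cover that spread, and what lies behind the excess stays open.

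The 6 libraries of a comparison of 3 against 3 make 10 splits, too few for a share under 0.05. For the mimic 1 of 10 splits, the real one, gave as many genes (377, highest other 0), as large a median of the genes that fell with TNF (0.074 in size, highest other 0.042), of endothelial identity (0.22, highest other 0.091) and of the cell cycle (0.35, highest other 0.17), and as large a site effect (0.042, highest other 0.018). For the number of lists called with the mimic at the preset correlation, 2 of 10 splits were as large (10, highest other 13). For TNF with nLDL against untreated 1 of 10 splits gave as many genes (8527, highest other 0) and as many lists (12, highest other 9). Every other split mixes libraries of both groups, so any difference between the groups, whatever its cause, widens the spread and shrinks the contrast. Lower values in the other splits are therefore partly built in, and no conclusion is drawn from them.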
